A study of Mus musculus with 3 samples.

How the data were processed

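The series holds 3 libraries of ribosome-depleted total RNA from the chromatin fraction of mouse bone-marrow-derived macrophages (strain C57BL/6J). All 3 belong to 1 condition. Per the labels, the cells were exposed to Lipid A (100 ng/ml) over 12 h, washed, and kept without it over another 12 h. A repeat dose of 100 ng/ml then followed, lasting 25 min. The labels number the libraries as biological replicates 1, 2 and 3 and list the same donor identifier for each. They do not say whether each replicate came from a separate animal, so the spread given here is that between these 3 libraries. The starting amount of RNA differed: 1 µg in replicate 1, 250 ng in replicate 2 and 500 ng in replicate 3. No untreated or once-stimulated sample was analysed here, so no difference between conditions was computed.

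Each library has 1 gene table and 2 transcript tables. Per the file headers, the gene table and the first transcript table carry expected counts, TPM (length-scaled abundance with the same total in every library) and posterior mean TPM, in columns named as the program RSEM names them. Per the file headers, the second transcript table carries estimated counts and TPM in columns named as the program kallisto names them. The deposited notes beside the files give mm10 as the genome build and GENCODE M21 as the annotation. They state that the first kind of table was derived from alignments to the transcriptome and the second from reads and a transcript index. The aligner, its version and the strand setting are not given in the sources used here. Antisense genes and genes of the annotation's class TEC that overlap another gene are therefore uncertain. Genes with near-identical copies are uncertain as well, because the expected counts of the deposited tables divide shared reads between copies. Of the 81881 rows in each gene table, 55536 are genes of GENCODE M21, and these were used. The other rows, spike-ins and identifiers made of digits only, held 1.75%, 0.396% and 0.239% of the expected counts in replicates 1, 2 and 3 and stayed out of totals and tests.

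Expected counts over annotated genes came to 13502401 in replicate 1, 17848798 in replicate 2 and 17824176 in replicate 3. A count of 0 allows up to 3 counts, which is 0.222, 0.168 and 0.168 CPM (counts scaled to library total) in the same order. This covers counting error only, since reads without molecular identifiers are not independent molecules. Replicates were compared before averaging with a chi-square statistic over genes. Per degree of freedom it was 175 for replicates 1 and 2, 97.4 for replicates 1 and 3 and 37.6 for replicates 2 and 3, so no pair agreed within sampling noise as repeats of 1 library could. Separate samples are expected to exceed that noise, and each library was counted as 1 replicate because the labels number it as one. The statistic included the ribosomal RNA locus on chromosome 17, with 1503296, 5667090 and 4427517 counts in replicates 1 to 3. Its size and the order of the pairs therefore reflect that locus in part.

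A gene was called detected at a TPM of at least 1 in every library. RNA classes are the gene types of the annotation. Before the data were examined, 26 gene lists (16 of pathways or RNA kinds and 10 of cell type markers) were fixed. So were the tests, the alternatives and the rule for naming genes, except for the additions named as such. For each list and library the median log2(TPM + 1) was taken, with a pseudocount of 1. Its percentile among 10000 random lists of the same size was computed from protein-coding genes, or from all annotated genes for the 2 lists of noncoding RNA. A list was called high where its percentile was at least 97.5 in every library. Genes are not replicates, so the percentile describes these libraries. Within-library differences between list medians were tested with an exact two-sided sign-flip test over the 3 libraries, for which the smallest possible p is 0.25.

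Expected counts were rounded to whole numbers for edgeR 4.0.16 (R 4.3.3). After filterByExpr and TMM normalization, estimateDisp was run with an intercept only. The square root of the dispersion is the biological coefficient of variation (BCV). Each list's median BCV was set against 10000 random lists matched on mean expression in 20 bins. For deviations per library, the log2 CPM of each gene were centred on the gene's mean over the libraries, with and without removal of the trend with GC content and transcript length in 20 bins each. The retained-intron share is the percent of a gene's transcript TPM in transcripts annotated as retained_intron. It was computed for genes with both a protein_coding and a retained_intron transcript and a gene TPM of at least 5 in every library. TPM of the second transcript table were summed per gene to compare both quantifications. Other tools were DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

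The list statistics were tested on simulated data. Over 15032 genes, 100 genes halved in 1 library had a median deviation of -0.66 on the log2 scale against a true -0.67. With a planted GC trend removed, it was -0.67. For 100 genes doubled in 1 library, the values were 0.62 and 0.63 against a true 0.67, an underestimate. Of 200 random lists of 20 genes, 2.5% passed the upper bound in replicate 1, the library used for this. They were drawn from the same genes as the comparison lists, so a share near 2.5% was certain beforehand. This tested the calculation alone and not the rule of passing in every library. A planted median retained-intron share of 39.9% was estimated at 39.4%. It was planted in transcript values, so this tested the summing alone and not how reads are divided between overlapping transcripts. For the spread between replicates, over 13794 simulated genes, a true BCV of 0.25 was estimated at 0.273 and a true BCV of 0.75 in 200 genes at 0.326. Single-gene BCV values are thus drawn strongly toward the trend, and they were used for ranking. Without shrinkage the same genes came to 0.198 and 0.577.

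Alternatives were other TPM minimums, another pseudocount, posterior mean TPM, the second quantification, CPM, TPM rescaled to nuclear protein-coding genes, other size factors and filters, DESeq2 dispersions and each replicate left out in turn. Some alternatives were added after the data were seen: BCV without shrinkage, class shares without the ribosomal RNA locus on chromosome 17, and, for single named genes, posterior mean and rescaled TPM. The agreement of the quantifications without each replicate was added as well. Named genes are the 4 members with the highest mean TPM in each list described and 15 genes fixed in advance. Not every gene that this rule selects is reported here. To these come the 10 protein-coding and 5 other genes with the highest mean TPM, the 5 genes with the highest BCV at a mean TPM of at least 10, and the genes with the largest retained-intron share (5 overall and 5 among list members). Of the list symbols, 2 were not matched in the annotation.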

Results

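RNA bound to chromatin was sequenced from mouse bone-marrow-derived macrophages, primary cells grown from marrow progenitors. The cells had met Lipid A, the part of bacterial lipopolysaccharide that the receptor TLR4 recognises, for 12 h. After a washout of 12 h they were stimulated again for 25 min, each time at 100 ng/ml. The chromatin fraction holds RNA still attached to its gene or retained in the nucleus. All 3 libraries, biological replicates 1 to 3, had this one treatment, so the values below describe levels within this state and how far the replicates differed. Annotated genes took 13502401, 17848798 and 17824176 expected counts in replicates 1, 2 and 3. Errors are SDs over the 3 libraries (n = 3) throughout, levels are in TPM (transcript abundance scaled to the same total in every library), and coordinates are those of GRCm38 (mm10).

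By expected counts, protein-coding genes took 61.1% ± 7.57 of the libraries and long intergenic noncoding RNA (lincRNA) 33.0% ± 7.62. Much of the latter was 1 ribosomal RNA locus and Malat1, a nuclear-retained lncRNA. The locus on chromosome 17, where Gm26917 (39843013 to 39846341), Gm42418 and the rRNA gene CT010467.1 lie side by side, took 11.1% of counts in replicate 1, 31.8% in replicate 2 and 24.8% in replicate 3. Malat1 (chromosome 19, 5795690 to 5802672) took 9.93%, 6.31% and 8.50%. By TPM, which divides by effective length, the order was different: small nucleolar and Cajal body RNA took 30.3% ± 1.94, protein-coding genes 27.2% ± 2.31, snRNA 13.1% ± 6.14, lincRNA 13.1% ± 5.02 and ribozyme and misc RNA 11.2% ± 4.41. Small nucleolar and Cajal body RNA held 0.345% ± 0.0294 of the counts, so its TPM share rests on few reads from short genes. Without the chromosome 17 locus, an alternative added after seeing the data, protein-coding genes took 79.0% ± 1.46 and lincRNA 14.7% ± 1.3 of counts.

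**Figure D1:**
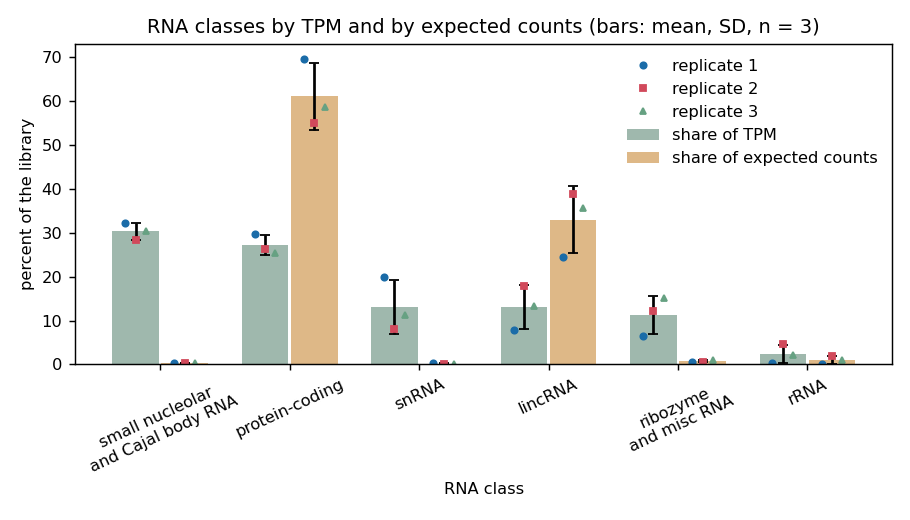
Share of each of the 6 largest RNA classes (x axis) in percent of the library (y axis), by TPM and by expected counts. Bars are means and SDs over 3 libraries and points are the replicates. Small nucleolar and Cajal body RNA stands at 30.3% of TPM and at 0.345% of counts.

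A TPM of at least 1 in every library was reached by 9689 of 22028 protein-coding genes, 295 lincRNA genes, 564 antisense genes and 78 small nucleolar or Cajal body RNA genes. The protein-coding gene with the highest mean was Mx1, an interferon-induced antiviral GTPase, at 1768 ± 746 TPM (chromosome 16, 97447035 to 97462907). It was followed by H2-K1, a class I major histocompatibility molecule, at 1472 ± 239, and by the inhibitory receptor gene Lilrb4a at 1324 ± 446. Tcirg1, a subunit of the vacuolar proton pump, stood at 1211 ± 239, Rsrp1 at 1196 ± 149 and the kinase gene Ikbke at 975 ± 95.9. Fyb (968 ± 111), the iron-storage gene Fth1 (941 ± 202), the transcription factor gene Zeb2 (921 ± 241) and the interferon-inducible gene Rnf213 (882 ± 52.9) completed the 10 highest. Together these 10 held 4.65%, 4.10% and 4.07% of protein-coding TPM in replicates 1 to 3. Among other genes the highest means were those of Rmrp, the RNA of RNase MRP (80396 ± 38192), the small nucleolar RNA genes Gm22988 (70507 ± 34143), Gm26447 (41714 ± 15160) and Snord15b (31957 ± 8556), and Gm26917 of the ribosomal locus (66838 ± 31879). The second quantification gave lower means for Rmrp (33525), Gm22988 (7373), Gm26447 (2110) and Snord15b (3550) and 77568 for Gm26917, so this ranking holds for the first quantification alone. H2-K1 belongs to a family of near-identical genes, and its level is uncertain for that reason. The ranking of protein-coding genes below Mx1 also holds for the first quantification alone. The second gave means of 1580 for Ikbke, 1555 for Lilrb4a, 1499 for Tcirg1 and 1126 for H2-K1. There the interferon-response gene Rsad2 (752) was above Fth1 (698) and Rnf213 (630).

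The NF-κB pathway and its feedback inhibitors formed one of the uniformly present response lists: all 15 members were detected, with a mean of the list medians of 5.29 ± 0.08 on the log2(TPM + 1) scale. The list lay at the 100th percentile of random protein-coding lists in each library, as did the housekeeping list. Of the 22028 genes drawn from, 9689 were detected, so this percentile tends to be high for expressed genes of any kind. Among detected genes alone the list's percentiles were 99.7, 99.8 and 99.9. Its highest members are genes that NF-κB itself induces. Tnip3 stood at 304 ± 131 TPM, Nfkbia, which encodes IκBα, at 236 ± 68.2 (chromosome 12, 55489410 to 55492647), Tnfaip3, which encodes the deubiquitinase A20, at 194 ± 73.5 (chromosome 10, 19000910 to 19015657) and Nfkbiz at 114 ± 49.1.

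Of the 24 immediate early genes, which need no new protein to be induced, 22 were detected. The list's median was 5.45 ± 0.27 (100th percentile in each library, and 100, 99.94 and 100 among detected genes alone). Mcl1, a survival gene of the Bcl2 family, was highest at 268 ± 63.0 TPM. The mRNA-destabilising protein gene Zfp36 followed at 178 ± 42.9, then the transcription factor genes Klf6 at 141 ± 43.0 and Junb at 132 ± 21. Fos (chromosome 12, 85473890 to 85477273) stood at 44.3, 87.0 and 121 TPM in replicates 1 to 3 and Egr1 (chromosome 18, 34859823 to 34864984) at 91.4, 38.5 and 53.3, so these 2 genes ranked the libraries differently.

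Cytokine and chemokine genes were split. Of 31 members, 19 were detected and 12 were not. Ccl5 stood at 256 ± 89.4 TPM, Tnf at 224 ± 84.3 (chromosome 17, 35199381 to 35202007), Cxcl10 at 197 ± 146, Cxcl2 at 147 ± 84.0 and Il1b at 106 ± 37.5 (chromosome 2, 129364570 to 129371139). In contrast, Il6 (chromosome 5, 30013114 to 30019981) was at 1.53, 0.21 and 1.77 TPM, from 41, 7 and 45 counts. Ifnb1 was at 2.49, 0.25 and 0.57 TPM from 18, 2 and 5 counts, and Il12b, a subunit of interleukin 12, at 0.18, 0.08 and 0.14 TPM from 4, 2 and 4 counts. Without a sample that had no pretreatment, it was not possible to say whether these low levels differ from those of a first response. The list's median was 3.53 ± 1.22, at the 100th percentile in replicates 1 and 3 and at the 94.5th in replicate 2. The list therefore met the bound of 97.5 in each library only without replicate 2, or with the second quantification. Against detected genes alone its mean percentile was 93.6, with replicate 2 at 80.9.

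**Figure D2:**
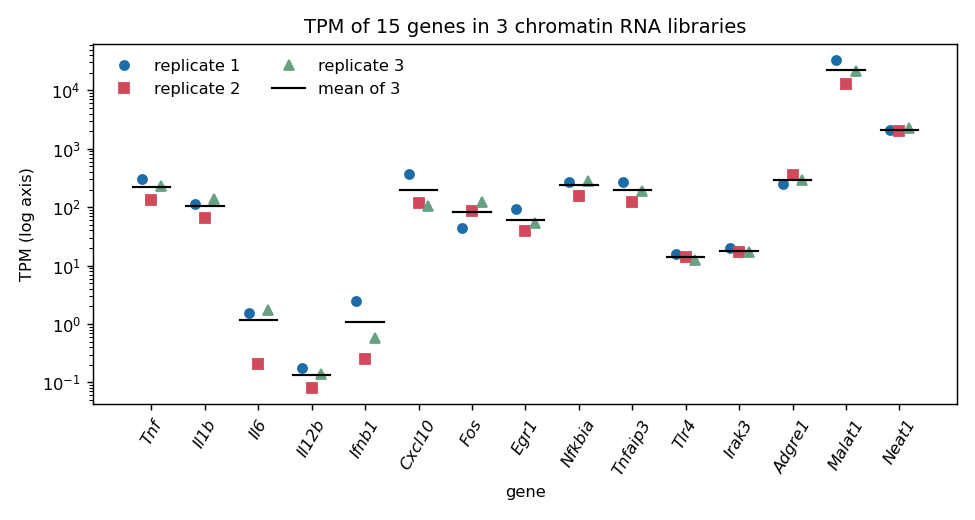
TPM (y axis, log scale) of the 15 genes fixed in advance (x axis) in each replicate, with the mean of 3 as a line. In the first quantification, shown here, Tnf, Nfkbia and Tnfaip3 lie near 200 TPM, with means from 194 to 236, and Il6, Il12b and Ifnb1 lie near or below 1 TPM, with means from 0.133 to 1.17.

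Interferon-response genes were the highest of the protein-coding response lists. All 28 members were detected, 18 of them at a mean of at least 100 TPM. The list's median was 7.27 ± 0.72 (100th percentile in each library, also among detected genes alone). After Mx1 came the transcription factor gene Stat2 at 585 ± 128 TPM, Oasl2, of the oligoadenylate synthetase family, at 492 ± 114 and the antiviral gene Rsad2 at 468 ± 274. Antimicrobial effector genes were detected for 12 of 16 members, with a median of 4.06 ± 0.37 and percentiles of 99.9, 99.6 and 100. Among detected genes alone the percentile was 100 in each library. The mitochondrial superoxide dismutase gene Sod2 stood at 411 ± 178 TPM, Acod1, the itaconate-producing enzyme, at 356 ± 213, the lysozyme gene Lyz2 at 191 ± 9.59 and the acute-phase gene Saa3 at 159 ± 56.0.

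The median of the TLR4 signalling components was even between libraries, while its members ranged from 2.98 (Tirap) to 151 TPM (Tbk1). All 22 members were detected with a median of 4.59 ± 0.06, at percentiles of 99.99, 100 and 100. Among detected genes alone the percentiles were 97.7, 98.8 and 99.2, closer to the bound of 97.5. In the first quantification the highest were Tbk1 (151 ± 40.3 TPM) and Cd14, the lipopolysaccharide co-receptor (105 ± 74.9). Chuk (76.4 ± 4.0) and Ikbkb (72.3 ± 1.40), both kinase subunits of the IKK complex, came next. Tlr4 itself (chromosome 4, 66827584 to 66930284) was at 14.1 ± 1.78. Negative regulators of TLR signalling were detected for 18 of 20 members with a median of 5.15 ± 0.05 (100th percentile in each library). Among detected genes alone the percentiles were 100, 99.95 and 100. They were led by Trafd1 at 508 ± 97.9, Tnfaip3, Zfp36 and the phosphatase gene Inpp5d at 177 ± 18. Many members also belong to lists above. Dusp1, Atf3 and Zfp36 are in the immediate early list, and Tnfaip3, Nfkb1, Nfkb2, Bcl3 and Cyld in the NF-κB list. The level of the negative regulators is therefore not independent of those lists. Irak3, which encodes the inhibitory kinase homologue IRAK-M, was at 18.1 ± 1.55.

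**Figure D3:**
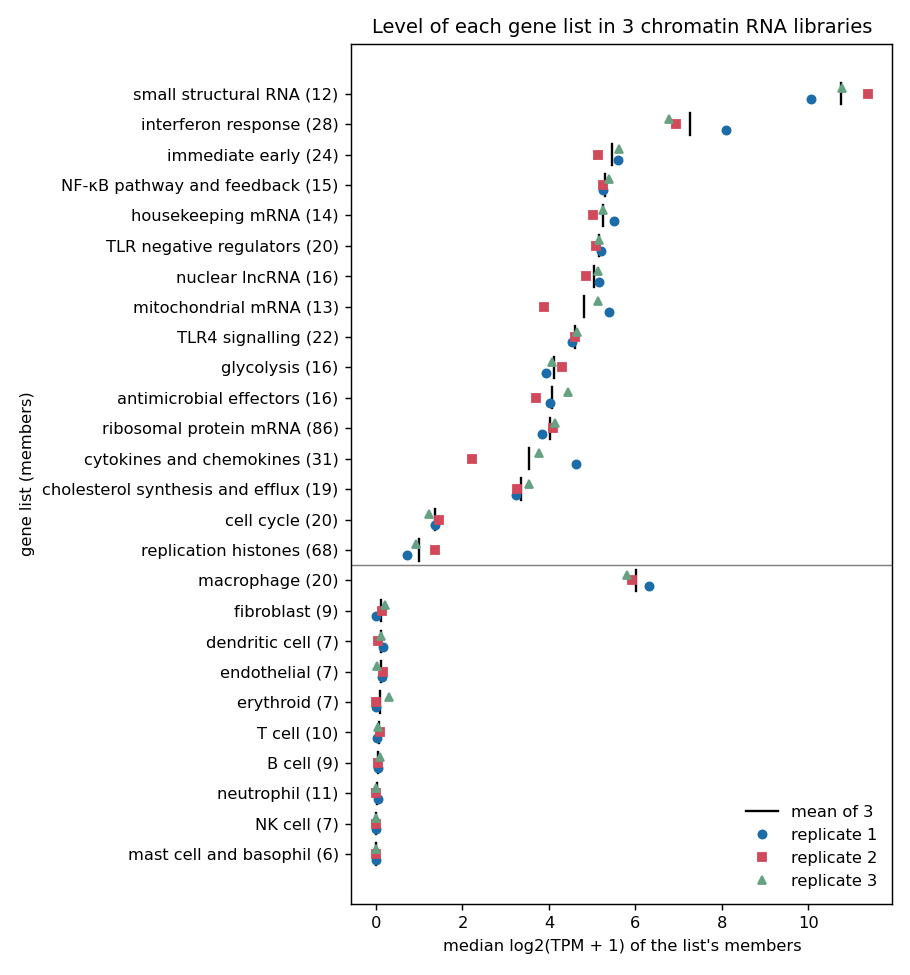
Median log2(TPM + 1) (x axis) of each fixed gene list (y axis, with the number of members matched), per replicate and as the mean of 3. Pathway lists are above the grey line and cell type lists below it. The macrophage list has a mean of 6.01, and the other 9 cell type lists lie between 0 and 0.12.

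Among the other lists, neither cell cycle nor replication histone genes passed a bound against random protein-coding lists. Of 20 cell cycle genes 11 were detected, with a median of 1.36 ± 0.11 and percentiles between 70.8 and 75.4. Pcna (19.7 ± 4.30 TPM), Mki67 (9.39 ± 3.67), Mcm6 (6.44 ± 1.04) and Top2a (4.46 ± 0.196) were its highest members. Of 68 replication histone genes 24 were detected (median 1.00 ± 0.33, percentiles 59.2, 86.5 and 69.9), led by Hist2h2aa2 at 19.4 ± 8.77, Hist3h2a at 18.2 ± 2.43, Hist1h4m at 14.4 ± 6.86 and Hist1h4k at 13.4 ± 11.2. Against detected genes alone the mean percentiles of these lists were 1.36 and 0.387. Histone genes are near-identical copies and their messages mostly lack a poly(A) tail. All 16 glycolysis genes were detected (median 4.11 ± 0.18), with Hk3 at 320 ± 47.0, Pkm at 109 ± 18.7, Pfkfb3 at 64.2 ± 19.0 and Gpi1 at 41.3 ± 8.35. Of 19 genes of cholesterol synthesis and efflux 18 were detected (median 3.35 ± 0.17). The exporters Abca1 (110 ± 15.6) and Abcg1 (71.8 ± 15.7), the sterol-sensing receptor gene Nr1h3 (56.8 ± 10.2) and Apoe (51.3 ± 8.53) stood above its other members. The glycolysis and cholesterol lists passed the upper bound against protein-coding genes in each library. Against detected genes alone they did not, with mean percentiles of 84.0 and 33.7.

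Housekeeping messages had a median of 5.26 ± 0.24, with Actb at 448 ± 134 TPM, Eef1a1 at 236 ± 17.9 and B2m at 83.0 ± 36.8. Ribosomal protein messages were detected for 81 of 86 genes at a lower median of 4.02 ± 0.16. Rpl10 (126 ± 13.8), Rps9 (105 ± 20.7), Rpl3 (80.5 ± 14.7) and Rps12 (47.9 ± 4.61) were the highest of these. Their mean percentile against detected genes was 97.0, below the bound. Nuclear lncRNA had a median of 5.05 ± 0.17, with Malat1 at 22285 ± 9858, Neat1, the scaffold of paraspeckles, at 2134 ± 154 (chromosome 19, 5824708 to 5845478), Xist, the X-inactivation RNA, at 960 ± 81.7 and Gas5 at 159 ± 3.65. Small structural RNA was highest of the 26 lists, at 10.74 ± 0.65, with Rmrp, Rn7sk at 13596 ± 4475, Rnu2-10 at 7886 ± 3035 and Rn7s1 at 7827 ± 2079. The second quantification gave lower means of 8173 for Rn7sk, 2720 for Rnu2-10 and 4001 for Rn7s1. These RNAs are short and, as Rn7s1 and Rn7s2 with equal values show, shared between copies. Mitochondrial messages had a median of 4.80 ± 0.81, led by mt-Co1 at 225 ± 86.4, mt-Atp8 at 145 ± 69.4, mt-Nd6 at 56.5 ± 30.1 and mt-Nd1 at 34.0 ± 15.5. The rank of mt-Atp8, a short gene, rests on 84, 22 and 55 counts in replicates 1 to 3, against 904, 427 and 936 for mt-Nd5. The genes mt-Co2 and mt-Atp6 had 0 counts in each library of the first quantification. Against detected genes the mitochondrial list had a mean percentile of 92.0, below the bound.

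Macrophage markers dominated over those of every other cell type listed. Of 20 members 19 were detected, with a median of 6.01 ± 0.26. The cathepsin gene Ctsb was at 394 ± 66.1 TPM, Adgre1, which encodes F4/80, at 298 ± 52.9 (chromosome 17, 57358691 to 57483527), Lyz2 at 191 ± 9.59 and the receptor gene Csf1r at 149 ± 28.9. In the first quantification no neutrophil, dendritic cell, NK cell, mast cell and basophil or fibroblast marker was detected in every library. In the second, Zbtb46 (1.64 ± 0.28 TPM) and Col1a1 (1.26 ± 0.22) had means above 1. The highest members of these lists were Ngp (0.41 ± 0.0794), Zbtb46 (0.86 ± 0.07), Ncr1 (0, 0 and 1 count), Ms4a2 (3, 1 and 0 counts) and Col3a1 (0, 16 and 18 counts). The collagen gene Col1a1 had 0, 32 and 42 counts and Col1a2 1, 23 and 17. Fibroblast transcripts at a trace level were thus seen in replicates 2 and 3 of the first quantification. For Col1a1, the SD in the second leaves no replicate near 0. Of the T cell list Cd28 (15.2 ± 6.06) and Cd5 were detected, of the B cell list Cd22 (5.32 ± 3.23), of the erythroid list Alas2 (9.25 ± 2.33) and of the endothelial list Vwf (28.0 ± 5.56), Kdr (9.44, 1.80 and 2.99 TPM) and Pecam1 (1.61 ± 0.526, and 8.12 in the second quantification). The other members of these lists, such as Cd3e, Hbb-bt and Cldn5, were below detection in the first quantification. Among them Cd8a of the T cell list was at 0.12 ± 0.08 TPM there and at 2.20 ± 0.34 in the second.

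Differences between lists were taken within each library, 13 in all. The interferon-response list exceeded the cytokine and chemokine list by 3.74 ± 0.88 on the log2(TPM + 1) scale, with a range over libraries from 3.02 to 4.72. The immediate early list exceeded it by 1.92 ± 0.98 (0.96 to 2.92) and the NF-κB list by 1.76 ± 1.21 (0.62 to 3.03). The negative regulators exceeded the TLR4 signalling components by 0.56 ± 0.10 (0.48 to 0.66). Macrophage markers exceeded the other 9 cell type lists by means from 5.89 (fibroblast) to 6.01 (NK cell, and mast cell and basophil). Each of the 13 differences was positive in 3 of 3 libraries, and each had p = 0.25 in the exact two-sided sign-flip test, the smallest that 3 libraries allow. No difference could therefore reach 0.05, with or without adjustment for 13 tests. With only the members at a TPM of at least 1 in every library, the first 3 of these differences were smaller, at 2.40 ± 0.86, 0.71 ± 0.42 and 0.43 ± 0.69. For the NF-κB list the SD then exceeded the mean difference. With TMM CPM they were larger, at 5.06, 3.09 and 3.37, and with the second quantification they were 3.26, 1.19 and 1.98. Without replicate 2 the NF-κB difference was 1.12. The difference between negative regulators and TLR4 signalling components was 1.02 with the second quantification. For the cell type lists with a member left at a TPM of at least 1 in every library, the macrophage differences were then 3.40 (T cell), 3.62 (B cell), 2.81 (erythroid) and 3.84 (endothelial). With a pseudocount of 0.1 they ran from 8.49 to 9.31 over the 9 lists. Log2 values with a pseudocount of 1 understate differences of low genes.

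The replicates ranked genes alike, and some lists spread more between them than matched random lists did. Over the 9689 detected protein-coding genes Pearson's r of log2(TPM + 1) was 0.962 for replicates 1 and 2, 0.974 for 1 and 3 and 0.977 for 2 and 3, across genes, which are not independent replicates. The common BCV from edgeR over 14193 genes was 0.209 and the median BCV of single genes 0.203. Without replicate 1 the median was 0.165. Cytokine and chemokine genes had a median BCV of 0.278, against 0.191 for matched random lists, interferon-response genes 0.241 against 0.180, immediate early genes 0.235 against 0.185 and NF-κB genes 0.20 against 0.181. These lay at the 100th, 100th, 100th and 99.5th percentile, and the NF-κB value was below the median of all genes. Mitochondrial messages (0.295), small structural RNA (0.259) and antimicrobial effectors (0.253) also lay at the 100th percentile. TLR4 signalling components (0.178, percentile 4.05) and macrophage markers (0.186, percentile 73.7) did not pass the upper bound. The calls of the first 4 lists depended on which libraries were included. That of the cytokine list was lost without replicate 3 (percentile 74.4), that of immediate early genes without replicate 2 (92.4) or 3 (23.5), that of NF-κB genes without replicate 2 (35.9) or 3 (83.4), and that of interferon-response genes narrowly without replicate 1 (97.2).

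The lists differed in which library stood apart. Of the 28 interferon-response genes 27 were highest in replicate 1, where their median deviation from the gene's mean was 0.52 on the log2 scale, against -0.22 in replicate 2 and -0.29 in replicate 3. Of 21 cytokine and chemokine genes tested, 16 were highest in replicate 1 and 17 lowest in replicate 2 (median deviations 0.53, -0.78 and -0.05). Of 24 immediate early genes 16 were lowest in replicate 2, and 12 each were highest in replicates 1 and 3. Of 15 NF-κB genes 12 were lowest in replicate 2. Of 8 mitochondrial genes tested all were highest in replicate 1 and lowest in replicate 2. Other lists went the other way: of 81 ribosomal protein genes 59 were lowest in replicate 1 (median deviation -0.17), and of 25 replication histone genes 16 were highest in replicate 2 (0.37). TLR4 signalling components deviated by a median of 0.02, -0.03 and -0.03. Deviations in general went with GC content, with Spearman's rho across 14185 genes of -0.486 in replicate 1, 0.464 in replicate 2 and 0.123 in replicate 3.

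**Figure D4:**
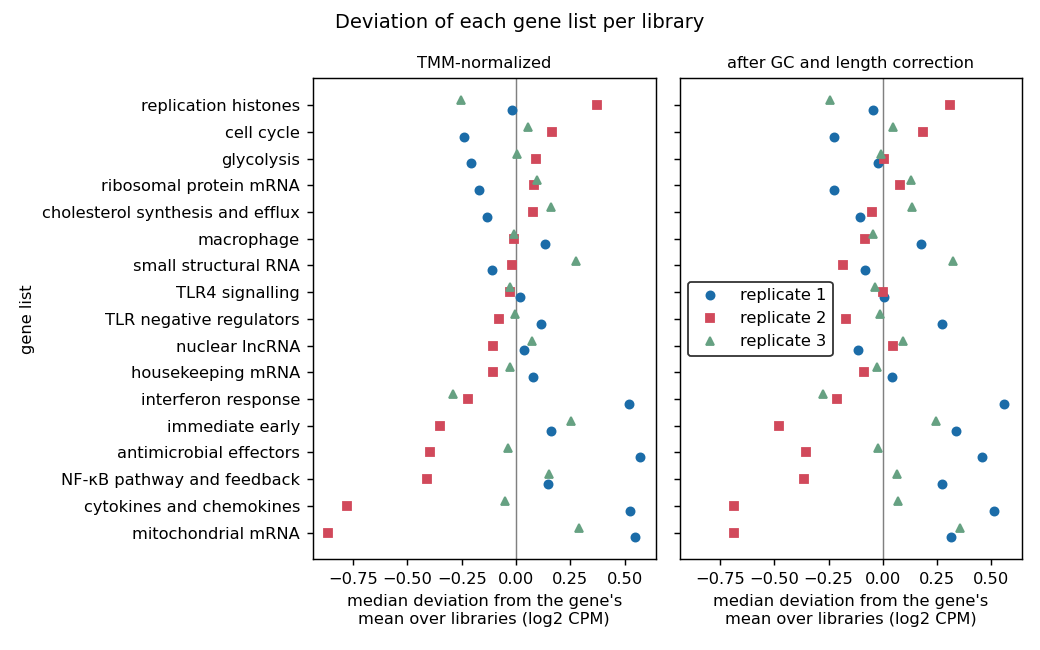
Median deviation of each list's genes from the gene's mean over the 3 libraries (x axis, log2 CPM) for each list (y axis) and replicate. The left panel uses TMM normalization alone and the right panel also removes the trend with GC content and length. The cytokine and chemokine list lies at -0.78 in replicate 2 on the left and at -0.69 on the right.

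The genes with the highest BCV at a mean TPM of at least 10 were mostly structural RNA. Rnu3a, Rnu3b4 and Rnu3b2, copies of the U3 small nucleolar RNA, were far higher in replicate 2 (935, 1515 and 1515 counts) than in replicate 1 (58, 167 and 167) or replicate 3 (53, 113 and 113). The equal values of the last pair show reads divided between copies. The mitochondrial ribosomal RNA mt-Rnr1 had 614, 26 and 228 counts. Gm49369 (chromosome 7, 142371096 to 142382667) had 473, 24 and 739 counts. It overlaps the cathepsin gene Ctsd on the same strand, which had 5077, 6711 and 5877, so its counts are uncertain. In the second quantification Rnu3a (1645 ± 173 TPM, against 961 ± 1459 in the first) and Gm49369 (238 ± 31.7, against 44.0 ± 36.7) differed far less between replicates. Rnu3b4 and Rnu3b2 (218 ± 378 each) and mt-Rnr1 (24.4 ± 27.4) still varied there by more than their means. An overlapping entry also named Rnu3a held more counts in the first quantification (343, 4436 and 562 in replicates 1 to 3). Overlapping entries named Rnu3b4 and Rnu3b2 had 14, 73 and 27 each. The smaller spread of Rnu3a in the second quantification covers the smaller entry alone, so it does not show that the excess in replicate 2 was absent.

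Transcripts annotated as retaining an intron carried nearly as much TPM as the other transcripts of their genes. Over 4730 genes with both kinds of transcript, the median retained-intron share was 46.9%, 47.7% and 43.2% in replicates 1 to 3 (46.0% ± 2.42). From transcript expected counts in place of TPM it was 29.0% ± 2.26. Cytokine and chemokine genes had a median share of 62.6% ± 4.84 over 6 genes, immediate early genes 56.5% ± 6.05 over 5 and interferon-response genes 48.4% ± 2.53 over 18. Negative regulators stood at 42.1% ± 1.37 over 12, NF-κB genes at 41.8% ± 3.87 over 12, TLR4 signalling genes at 47.5% ± 5.11 over 16 and macrophage markers at 30.8% ± 2.37 over 6. None of these lay above the 97.5th or below the 2.5th percentile of random lists in each library. Ribosomal protein genes (54.0% ± 4.48 over 59) lay at percentiles of 91.2, 99.9 and 98.7. With the second quantification the median share was 44.5% ± 1.32 over all genes. It was then 51.4% ± 1.77 for cytokine and chemokine genes, 52.7% ± 3.23 for immediate early genes and 53.1% ± 2.28 for ribosomal protein genes. In the first quantification the largest shares belonged to Krtcap3 (100% in each library), Lilrb4a (99.5% ± 0.261), Bbs10 (99.2% ± 1.36), Ifi27 (98.7% ± 2.19) and the fatty acid transporter gene Slc27a1 (98.6% ± 1.23). Among list members they belonged to Rps26 (98.0% ± 3.38), Rpl5 (96.2% ± 1.88), the phosphatase gene Dusp1 (95.5% ± 1.62), Tnip3 (94.9% ± 0.779) and Rpl10a (94.0% ± 1.59). The second quantification gave lower means for Krtcap3 (85.4%), Ifi27 (88.1%), Slc27a1 (90.5%), Rpl5 (81.5%), Dusp1 (93.7%) and Tnip3 (85.3%). It gave 99.8% for Lilrb4a, 100% for Rps26, 94.4% for Rpl10a and no value for Bbs10. How short reads divide between overlapping transcripts is a model estimate, so a share near 100% shows which annotated transcript took the reads and is no direct count of introns.

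The ranks of both transcript quantifications were closer over genes that both placed at a TPM of at least 1 than over all genes. Spearman's rho of TPM summed per gene was 0.769, 0.763 and 0.764 in replicates 1 to 3 over 55536 genes, and Pearson's r of log2(TPM + 1) was 0.821, 0.819 and 0.822. Over genes at a TPM of at least 1 in both, rho was 0.901, 0.897 and 0.895. A TPM of at least 1 was reached in the second quantification alone by 8236, 7481 and 8031 genes, and in the first alone by 166, 386 and 272. Levels of single genes depended on the quantification as well. Of the 105 genes at a mean TPM of at least 1 that the naming rule selects, 19 had a mean more than 1.5 times higher in the second and 13 one more than 1.5 times lower. The second gave mean TPM of 414 for Nfkbia, 298 for Tnfaip3, 265 for Tnf, 202 for Il1b, 229 for Klf6, 752 for Rsad2, 244 for Tbk1, 591 for Hk3, 105 for Pfkfb3, 153 for B2m, 261 for Csf1r and 21 for Alas2, each above its mean in the first. Inpp5d was higher in the second as well (272). Lower means in the second were 59.7 for mt-Atp8, 26.3 for Rps12, 11.2 for Hist2h2aa2 and 8.23 for Hist1h4m, among others. The correlations above are across genes, which are not independent replicates.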

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

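Signal was present in rows outside the genes reported on, and with no control sample it was set against the 3 counts that a count of 0 allows. The row for the phage phiX174, whose DNA is a common sequencing control, held 240517 expected counts in replicate 1, 71021 in replicate 2 and 42599 in replicate 3, or 1.75%, 0.396% and 0.238% of all rows. The rows for the ERCC spike-in RNAs held 0 in each library. Rows whose identifier is a number without a gene name held 39, 17 and 26 expected counts in replicates 1 to 3. No explanation was tested for either, and groups of 3 libraries were not screened for single outlying values.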

How the results depend on the processing

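The alternatives without shrinkage of the BCV and without the chromosome 17 locus, and those of single genes with posterior mean or rescaled TPM, were chosen after the data were seen. No paired analysis was possible because there is 1 condition. The 13 differences between lists kept their direction under every alternative run, and no result reversed. With a replicate left out, that direction was certain beforehand, since each difference was positive in every library. For the 4 response-list differences the values without a replicate ran from 0.50 to 4.09. Of the comparisons behind the main results, 239 were unchanged by the rule used. They stayed on their side of the bound, within the SD between replicates or, for counts of genes, within 1.5 times the main count. For the 13 differences between lists the rule was the same sign alone, whatever the size. The macrophage minus T cell difference (5.95 ± 0.28, and 8.82 with a pseudocount of 0.1) was thus among the unchanged. A further 18 moved outside these limits, 6 were weaker and 2 stronger. For single genes and other lists the numbers were 882, 246, 10 and 10. Part of the unchanged outcomes with a replicate left out could not have been different. A class share averaged over the remaining libraries always lies within the SD of the full mean. A list above the bound in every library also stays above it in those that remain. Such outcomes do not show that a result is stable, and they are included in the numbers above.

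Class shares moved most with the unit. From the second quantification protein-coding genes took 38.2%, small nucleolar and Cajal body RNA 6.74% and snRNA 5.22%. From expected counts the shares were 61.1%, 0.345% and 0.173%, and 33.0% for lincRNA. Without the chromosome 17 locus they were 79.0%, 0.451% and 0.212%, and 14.7% for lincRNA. Effective length enters TPM alone, and the other causes were not tested. Genes detected numbered 12782 in all, 7728 at a TPM of at least 5, where fewer can pass, 19783 in the second quantification and 17565 with posterior mean TPM, where the causes were not tested. Of protein-coding genes 9689 were detected, 11833 in the second quantification and 11096 with posterior mean TPM. The cytokine list's mean percentile was 99.6 with the second quantification, 96.6 with TMM CPM, 93.6 with detected genes alone and from 97.3 to 100 with each replicate left out. Median BCV was 0.279 without a filter, since low-count genes entered, 0.136 without shrinkage, and from 0.165 to 0.240 with each replicate left out. With each replicate left out, the percentile of the list's median BCV ran from 23.5 to 100 for immediate early genes, from 35.9 to 100 for NF-κB genes, from 74.4 to 100 for cytokines and chemokines and from 97.2 to 100 for interferon-response genes, with 2 libraries in each fit. The retained-intron share was 29.0% from transcript expected counts, which are not divided by length. Spearman's rho between quantifications was 0.897 over genes at a TPM of at least 1 in both, where genes that one of them puts below 1 are left out, and 0.753 without retained_intron transcripts, where the cause was not tested. Depth limits genes with a few counts, such as Il12b, Ifnb1 and most markers of other cell types. No neutrophil, dendritic, NK, mast cell or fibroblast gene was left at a TPM of at least 1, so that setting gave no value for those lists.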

Other observations

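The tests on the cytokine genes were chosen only after the pattern was seen, and the tests on the mitochondrial and small nucleolar RNA genes were chosen before their results were seen. Genes named only in this part were chosen after their values were seen.

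Members of the same list did not rank the libraries alike. The immediate early genes Fosb (0.5, 2.22 and 6.82 TPM) and Nr4a1 (3.90, 5.16 and 12.8) were highest in replicate 3, as Fos was, while Plk2 (193, 50.1 and 109) and Atf3 (56.4, 21.4 and 31.1) were highest in replicate 1. Cd14 stood at 57.5, 65.8 and 191 TPM, while the median of the TLR4 signalling genes hardly differed between libraries. Among chemokines, Cxcl1 (12.9, 3.64 and 31.8) and Cxcl2 (153, 59.7 and 227) were highest in replicate 3, and Cxcl10 (365, 119 and 106) and Cxcl11 (5.10, 0.47 and 0.51) in replicate 1. Il10, an anti-inflammatory cytokine, was at 23.7, 5.47 and 12.6 TPM.

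The labels state that sex was not collected. Xist, which is transcribed from the inactive X chromosome of female cells, had 175519, 186790 and 182252 counts in replicates 1 to 3. The 4 Y-linked genes Kdm5d, Uty, Ddx3y and Eif2s3y had 0 counts in each library. Together these values argue against male cells as the source of any of the 3 libraries.

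The lower level of cytokine and chemokine genes in replicate 2 (median deviation -0.78 on the log2 scale, 17 of 21 genes lowest there) was set against 2 technical explanations. Libraries differed in GC content bias, but with the trend with GC content and length removed the median deviation was still -0.69, with 20 of 21 genes below 0 and a percentile of 0 among matched lists, which argues against that bias as the whole cause. Less mature cytoplasmic mRNA of every kind in replicate 2 would lower ribosomal protein genes too. Their median deviation there was 0.081 (quartiles -0.02 and 0.25), so that drop was not seen. Mitochondrial messages were lower in replicate 2 (-0.86), and housekeeping messages had a median deviation of -0.11. The retained-intron share of ribosomal protein genes was higher there (59.2%, against 52.0% and 50.9%). Their level can thus include more unspliced RNA, so this test cannot tell whether their mature mRNA fell. The starting amount of RNA (250 ng in replicate 2) and the strength or timing of the response may also differ between the cultures, and with 1 library at each amount neither was tested. The ribosomal RNA locus held 11.1%, 31.8% and 24.8% of counts in replicates 1 to 3, and its bearing was not tested.

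In the first quantification mt-Co2 and mt-Atp6 had 0 counts and mt-Co3 2, 2 and 2, while the second gave mt-Co2 162, 0 and 287, mt-Atp6 577, 258 and 513 and mt-Co3 476, 55 and 690 estimated counts. Thus mt-Co2 was at 0 in replicate 2 in both. A candidate explanation is reads shared with near-identical nuclear copies. In line with it, 3 pseudogenes on chromosome 1, Gm28661 (24614885 to 24615565), Gm10925 (24613974 to 24614651) and Gm28437 (24613189 to 24613971), share at least 80% of the 31-base words of one of these genes and held 1875, 1089 and 1757 expected counts together. The genes mt-Nd3 (43, 0 and 0 counts in the first quantification) and mt-Nd4l (60, 0 and 56) have such copies too. The 8 mitochondrial protein-coding genes without such a copy had at least 22 counts in each library. Which copy the reads came from stays open, and no biological explanation was tested.

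The share of small nucleolar and Cajal body RNA in TPM (30.3% ± 1.94) was set against the short effective length that enters TPM. With the annotated length in its place the share was 5.50%, 4.78% and 4.11% in replicates 1 to 3. The bound set beforehand for this cause was under 5% in each library, which replicate 1 missed, and the bound against it, over 20%, was not met either. The length used thus moved most of the share, and how much of the remainder is RNA abundance cannot be told apart from fragment selection, since the libraries kept a size range of 250 to 400.

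On the log2(TPM + 1) scale 187 protein-coding genes were more than 8-fold apart between both quantifications in every library, of which 185 were higher in the second. Many were listed at 0 in the first, such as Vmn1r59, a pheromone receptor gene, and Olfr635, an odorant receptor gene. Others were above 1 TPM in both, such as Klf10 (7.96, 6.38 and 5.17 TPM in the first, 155, 426 and 226 in the second) and Cmklr1 (9.07, 8.73 and 5.14, against 166, 94.3 and 85.4). AC149090.1 was at 205, 274 and 225 TPM in the first and at 0 in the second. Which quantification is closer to the RNA present was not tested.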
